A study of Homo sapiens with 15 samples.

How the data were processed

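HEK293T cells, a human embryonic kidney line, carried short hairpin RNAs against 1 of 6 genes or a control hairpin, and RNA was sequenced from 15 libraries. There were 3 libraries of shControl and 2 each of shHDAC1, shPABPN1, shPCBP2, shSF3B4, shU2AF2 and shZNF384. Per the labels, nuclear RNA was isolated with a Vazyme kit, RNA was purified with a total RNA kit, messenger RNA was captured on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit. The labels name both nuclear and total RNA, so which of these the libraries hold is left open.

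The deposited table gives 1 PDUI value per transcript and library in the unit fraction, from 0.001 to 1, as the authors computed it. PDUI, the percentage of distal poly(A) site usage index, is the estimated share of a gene's transcripts that end at the distal of its poly(A) sites. A value of 1 stands for distal use alone, and a low value for mostly proximal use. The table holds 13056 transcripts of 13056 genes, 1 transcript per gene, on genome build hg38. Values have 2 decimals, apart from 1287 entries at 0.001, and entries without a value are marked as missing. The aligner, the program that called the sites and the gene annotation are not given in the sources used here. The table has no read counts, so the depth behind each value is unknown, and no interval or detection floor that needs a depth is given. PDUI does not measure how much RNA a gene makes, so the strength of each knockdown could not be checked.

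Libraries were grouped by their titles. For shSF3B4 the titles and library names number the replicates differently, so these columns were assigned to the group and not to a single sample. The library names of shControl carry a suffix, nuc, that the knockdown library names lack, and its meaning is not stated. If it marks another preparation, every comparison with shControl is confounded with it. Whether replicates came from separate cultures is not stated either, so the p-values measure only the spread between samples.

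Values entered limma 3.58.1 in R 4.3.3 as deposited, without a pseudocount or normalisation. All 15 libraries were fitted together with 1 mean per group, and variances were moderated with eBayes and a trend on the mean. The fit had 8 residual degrees of freedom, and the prior added 1.06. In 519 genes no group had any spread, and without them the prior was 2.36. A gene was tested in a comparison when it had a value in both knockdown libraries and in at least 2 of the shControl libraries. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison. A change was called at an adjusted p under 0.05. The same fit gave the contrast of the mean of all 6 knockdowns with shControl, the contrast of each knockdown with the mean of the other 5, the differences between pairs of knockdowns and a moderated F-test among the 6 knockdowns. Library means over the 11353 genes with a value in every library were compared by exact two-sided permutation tests.

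The main comparisons, tests, thresholds, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those stated below to be chosen later. By that rule, named genes are those with an adjusted p under 0.05 whose knockdown libraries all lie beyond the range of the control libraries. From these were taken the 10 with the largest rise and the 10 with the largest fall per knockdown, or all of them where fewer passed. Up to 4 called members of each gene list with the smallest p, the 6 targeted genes in every group, the 10 genes with the smallest adjusted p for all knockdowns together and the 10 with the smallest p among knockdowns were added. Genes named for moving in opposite directions, and gene families named among the other observations, were chosen after their values were seen. The differences between pairs of knockdowns and the counts of shared calls were not among the choices made beforehand.

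The gene lists covered cleavage and polyadenylation factors, SR proteins, hnRNP and KH-domain proteins, U2 snRNP and 3' splice site factors, HDAC corepressor complexes, nuclear RNA decay and export, the microRNA pathway, known 3' UTR polyadenylation targets, neurodevelopmental disorder genes, neurodegeneration genes, Rab and vesicle traffic, ubiquitin ligases and E2 enzymes, oxidative phosphorylation and the cell cycle. A list of markers of other cell types had 2 of its 20 genes in the table and was not tested. The other 14 lists were tested in each knockdown with camera (limma) at a preset correlation between genes of 0.01, with an estimated correlation, and with fry, adjusted over 84 tests. The number of called members was also counted with p-values adjusted over the list alone. Several genes stand in more than 1 list.

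Transcripts were matched to GENCODE release 29 by identifier. Of the 13056 transcripts, 97.3% were found there and 54.9% had the same version, and coordinates of last exons come from that release. The last exon was known for 97.3% of transcripts and overlapped an exon of another gene in 25.6% of these. Whether the libraries keep the strand is not given in the sources used here, so PDUI of a gene with such an overlap is uncertain. The correlation of knockdown effects was compared with 20 simulations of unchanged groups that share the control libraries.

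The fit was tested on simulated data in which 200 genes were given a known change. A change of 0.1 was recovered in 0% to 5.1% of genes, a change of 0.2 in 15.4% to 33.8% and a change of 0.3 in 38.1% to 64.1%, depending on the knockdown. Between 6.5% and 16.1% of the calls in these simulations were false, which exceeds the 5% aimed at. These recovered and false shares hold for the simulated genes and their spread only. In the measured data 499 of 661 shSF3B4 calls had a mean PDUI under 0.5. A control library had the lowest array weight there (0.373). The simulated shares were not shown to carry over to such genes or to that library, so they are no estimates for the measured calls. Alternatives were a logit scale, other filters on missing values, other variance priors, array weights, libraries centred on their medians, fits of only 2 groups, a replicate block, a reference of the other knockdowns, minimum changes of 0.1 and 0.2, and each library left out in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.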

Results

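Use of distal poly(A) sites was measured in 15 RNA sequencing libraries of HEK293T cells that carried a short hairpin RNA, either a control or one against a candidate regulator of alternative polyadenylation. The groups were shControl with 3 libraries and shHDAC1, shPABPN1, shPCBP2, shSF3B4, shU2AF2 and shZNF384 with 2 libraries each. The measurement was PDUI, the share of a gene's transcripts estimated to end at the distal site, given as a fraction for 13056 genes. Each library lacked a value for 1.37% to 4.49% of the genes, and 11353 genes had a value in all 15. The depth of the libraries is unknown, since the table gives fractions without read counts. The design text names 5 of the knockdowns as regulators of polyadenylation, and ZNF384 appears in the sample labels alone. Values below are group means ± SD over 3 shControl and 2 knockdown libraries unless another n is given.

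Mean PDUI over the complete genes was lowest in shControl replicate 1, at 0.522, while the other control libraries stood at 0.560 and 0.561. The group means were 0.548 ± 0.0224 in shControl (SD, n = 3) and, with n = 2 each, 0.536 ± 0.0044 in shPABPN1, 0.556 ± 0.0011 in shHDAC1, 0.566 ± 0.0053 in shSF3B4, 0.566 ± 0.0062 in shU2AF2, 0.570 ± 0.0058 in shPCBP2 and 0.582 ± 0.0053 in shZNF384. No knockdown differed from shControl in this mean by an exact two-sided permutation test. The lowest p was 0.1, for shZNF384, which is the smallest that 10 splits of 5 libraries allow. Over the tested genes, the median difference from shControl was −0.0093 in shPABPN1, 0.0033 in shHDAC1, 0.0117 in both shSF3B4 and shU2AF2, 0.015 in shPCBP2 and 0.0233 in shZNF384. With libraries centred on their medians, all 6 median differences changed sign, to values between −0.0233 and 0.0117. Centring subtracts 1 constant from all genes of a library, so these signs follow from the constants and give no direction of change. Here and below, a gene or list with a difference smaller than the constant turns direction by construction. Such a turn is no evidence for or against its change. Pairs of libraries of 1 group correlated across genes at r = 0.928 to 0.953, and pairs from different groups at r = 0.890 to 0.949, where genes are not independent replicates.

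**Figure D1:**
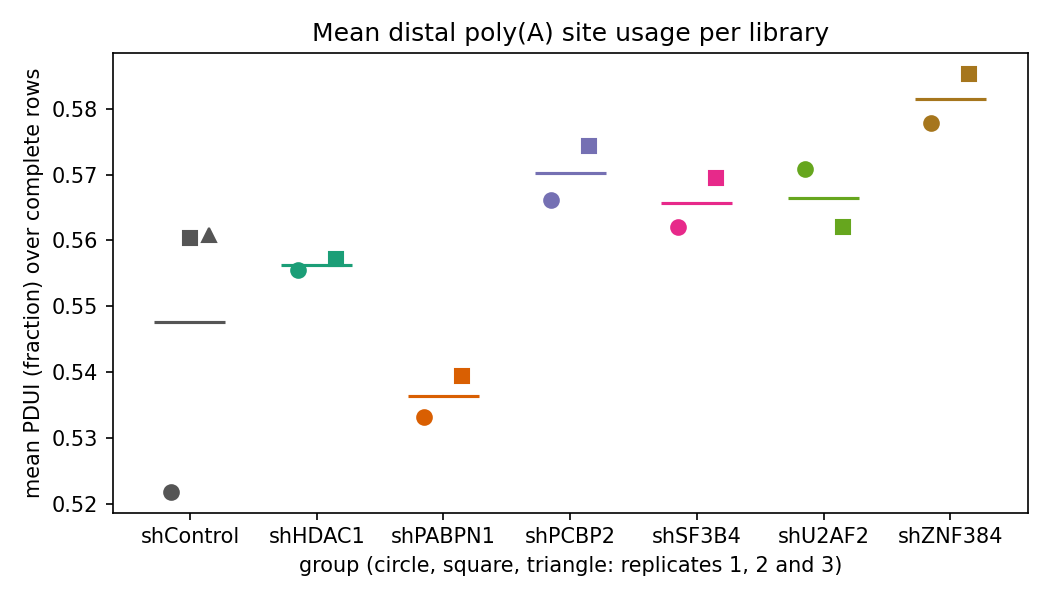
Mean PDUI (fraction, y axis) of each library over 11353 genes, by group on the x axis, with a symbol per replicate and a line at the group mean. ShControl replicate 1 at 0.522 lies below every other library, and the shZNF384 libraries at 0.578 and 0.585 lie above them.

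PDUI of the 6 targeted genes was examined in every group. HDAC1, a histone deacetylase, rose from 0.777 ± 0.093 in shControl to 1 ± 0 in shU2AF2 (limma, adjusted p = 0.0327). That was the only call among the 36 comparisons of the 6 targeted genes with shControl. In the cells where each gene was itself targeted, HDAC1 stood at 0.775 ± 0.007, PABPN1 at 0.535 ± 0.064, PCBP2 at 0.59 ± 0.014, SF3B4 at 0.555 ± 0.007, U2AF2 at 0.455 ± 0.049 and ZNF384 at 0.79 ± 0. The shControl values of the latter 5 were 0.513 ± 0.045, 0.57 ± 0.01, 0.533 ± 0.045, 0.413 ± 0.047 and 0.713 ± 0.1. None of these own-gene differences passed the test. PDUI gives the choice of the site and not the amount of RNA.

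The comparison of shSF3B4 with shControl asks how the choice of poly(A) site differs in cells with a hairpin against SF3B4, a subunit of the SF3b complex of the U2 snRNP. EGFR, a receptor tyrosine kinase, rose from 0.33 ± 0.053 to 0.935 ± 0.078, a difference of 0.605 (SE 0.069, limma, adjusted p = 0.00107). Its last exon lies on chromosome 7 from 55205256 to 55211628. AGO3, an Argonaute protein that binds microRNAs, rose from 0.383 ± 0.081 to 0.87 ± 0.085, and PEX16, a peroxisome biogenesis factor, from 0.24 ± 0.056 to 0.705 ± 0.021. ZNF264, a zinc finger gene, fell from 0.843 ± 0.107 to 0.395 ± 0.035. The largest fall, of AL353708.3 from 1 ± 0 to 0.295 ± 0.106, was in a non-coding gene whose last exon overlaps TOR1AIP1.

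Other large rises after SF3B4 knockdown were ZNF546 from 0.33 ± 0.036 to 0.9 ± 0, the non-coding EIF2AK3-DT from 0.437 ± 0.08 to 1 ± 0, FAM151B from 0.43 ± 0.156 (n = 2) to 0.965 ± 0.049, AC142472.1 from 0.427 ± 0.099 to 0.895 ± 0.148, and NOL9, a ribosomal RNA processing kinase, from 0.437 ± 0.038 to 0.925 ± 0.021. AP2A1, a subunit of the clathrin adaptor AP-2, rose from 0.127 ± 0.049 to 0.805 ± 0.007, and VPS53, a subunit of a Golgi tethering complex, from 0.34 ± 0.085 to 1 ± 0. DDHD1, a phospholipase, fell from 0.66 ± 0.04 to 0.2 ± 0.014, RAB6B, a Golgi Rab GTPase, from 0.943 ± 0.06 to 0.53 ± 0.057, and ZNRF1, a ubiquitin ligase, from 0.93 ± 0.075 to 0.545 ± 0.049. The last exons of these latter 5 genes overlap an exon of another gene, so their values are uncertain. Of the remaining large falls, AC011330.2 stood at 0.34 ± 0.113 and AC009061.2 at 0.6 ± 0.184, while AC026471.1, AC004264.1 and AL117339.5 overlap ARMC5, LIF and HSD17B7P2.

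Of 20 tested SR protein genes, which act in splicing, 1 rose and 3 fell in shSF3B4, and 16 did not pass. SRSF10 fell from 0.523 ± 0.015 to 0.255 ± 0.007, SREK1 from 0.3 ± 0.01 to 0.16 ± 0 and SRSF11 from 0.207 ± 0.006 to 0.14 ± 0.014, while the rise of SRSF3 from 0.05 ± 0 to 0.065 ± 0.007 turned to −0.013 with libraries centred. Adjusted over the list alone, 2 rose and 5 fell. Of 44 genes for ubiquitin ligases and E2 enzymes, 7 rose and 2 fell, or 9 and 2 adjusted over the list alone. TRIM33 fell from 0.957 ± 0.035 to 0.61 ± 0.057 and UBE2H fell from 0.993 ± 0.012 to 0.83 ± 0.028, while the rise of SKP1 to 0.05 ± 0 turned to −0.008 with libraries centred. Of 46 neurodevelopmental disorder genes, 3 rose and 4 fell, or 6 and 6 adjusted over the list alone. TSC1, an inhibitor of mTOR signalling, rose from 0.603 ± 0.032 to 0.985 ± 0.021 and ASXL3 from 0.277 ± 0.058 to 0.725 ± 0.049. GIGYF2 fell from 0.343 ± 0.038 to 0.155 ± 0.021, with a last exon that overlaps SNORC.

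Of 39 known 3' UTR polyadenylation targets, 3 rose and 1 fell in shSF3B4, with the same counts adjusted over the list alone. RHEB, a small GTPase, rose to 0.14 ± 0 from 0.1 ± 0.01. Of 33 neurodegeneration genes, 3 rose and 1 fell, the same adjusted over the list alone, among them HTT, the huntingtin gene, from 0.18 ± 0.01 to 0.305 ± 0.021. Of 20 microRNA pathway genes, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, and the fall was that of CNOT6, a deadenylase, from 0.663 ± 0.038 to 0.455 ± 0.007. Of 27 cleavage and polyadenylation factors, 1 rose and 2 fell, the same adjusted over the list alone. WDR33 rose from 0.18 ± 0.017 to 0.25 ± 0.028, PPP1CB fell from 0.437 ± 0.038 to 0.295 ± 0.021 and CPSF6, a subunit of cleavage factor I, from 0.597 ± 0.04 to 0.415 ± 0.007, where all 3 overlap another gene. In the U2 snRNP list 2 of 26 rose, SF3B1 from 0.057 ± 0.006 to 0.11 ± 0 and SF3A1 from 0.247 ± 0.006 to 0.31 ± 0.014, and 3 rose adjusted over the list alone.

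Among the other lists in shSF3B4, 3 of 37 hnRNP and KH-domain genes rose, HNRNPDL from 0.287 ± 0.055 to 0.42 ± 0.014, HNRNPA3 to 0.335 ± 0.007, and HNRNPD to 0.08 ± 0, which turned to −0.002 with libraries centred. Against the other knockdowns HNRNPA3 was lower, by −0.054. Of 31 nuclear RNA decay and export genes, 2 rose and 1 fell, CHTOP from 0.377 ± 0.025 to 0.535 ± 0.021, THOC5 to 0.055 ± 0.007, at −0.007 with libraries centred, and EXOSC6, an exosome subunit, down from 0.257 ± 0.006 to 0.21 ± 0. Of 37 oxidative phosphorylation genes 3 rose, UQCRB from 0.013 ± 0.006 to 0.07 ± 0.014, with NDUFA9 and COX7B at −0.018 and −0.007 with libraries centred. These 3 lists had the same counts adjusted over the list alone. Of 44 cell cycle genes 2 rose, CDT1, a replication licensing factor, from 0.24 ± 0 to 0.405 ± 0.021 and CCNB1 from 0.283 ± 0.032 to 0.375 ± 0.007, and 3 rose adjusted over the list alone. Of 32 HDAC corepressor genes SAP18 rose to 0.135 ± 0.007 and NCOR1 fell from 0.293 ± 0.023 to 0.195 ± 0.021, and 4 rose and 1 fell adjusted over the list alone. Of 59 Rab and vesicle traffic genes, SNX2 rose to 0.08 ± 0 from 0.047 ± 0.006, also the 1 call adjusted over the list alone.

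By fry, which tests a list without setting it against other genes, the polyadenylation targets, oxidative phosphorylation and ubiquitin lists were higher in shSF3B4 (adjusted p = 0.0302, 0.0302 and 0.0336), and all 3 turned lower, without passing, with libraries centred. In all, limma called 661 of 12195 genes in shSF3B4, 520 higher and 141 lower, and 410 of them differed by at least 0.1. No list passed camera. Without shControl replicate 1, 536 genes were called, 396 higher and 140 lower, and 474 of the 661 kept their call. In the lists above, the members called without that library, as rises and falls, were 0 and 5 SR proteins, 5 and 2 ubiquitin genes, 4 and 3 neurodevelopmental genes, 3 and 1 polyadenylation targets, 2 and 1 neurodegeneration genes, 2 and 1 microRNA pathway genes, 1 and 2 cleavage factors, 2 and 0 U2 snRNP genes, 3 and 0 hnRNP genes, 2 and 1 RNA decay and export genes, 4 and 0 oxidative phosphorylation genes, 1 and 1 cell cycle genes, 1 and 1 corepressor genes, and 1 and 0 traffic genes. Of the genes named for shSF3B4, RAB6B, RHEB, CCNB1, SRSF3, CPSF6 and AC009061.2 lost their calls there (adjusted p = 0.05 to 0.121). With libraries centred on their medians 210 genes were called, 111 higher and 99 lower, with only these 2 groups in the fit 186, and without shSF3B4 replicate 2 there were 429. Of the 661 differences, 27 changed direction with libraries centred, and 443 of the calls also passed against the other 5 knockdowns.

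The comparison of shU2AF2 with shControl concerns U2AF2, the large subunit of the factor that binds the polypyrimidine tract at 3' splice sites. KIN, a DNA- and RNA-binding protein, rose from 0.183 ± 0.032 to 0.875 ± 0.064, a difference of 0.692 (SE 0.064, limma, adjusted p = 0.000222). Its last exon lies on chromosome 10 from 7750962 to 7756142. TMEM25, a membrane protein, rose from 0.167 ± 0.012 to 0.895 ± 0.092, YIPF4, a Golgi membrane protein, from 0.147 ± 0.012 to 0.795 ± 0.134, and CFD, complement factor D, from 0.237 ± 0.05 to 0.885 ± 0.163. KIF3C, a kinesin motor, fell from 0.677 ± 0.085 to 0.275 ± 0.092, and AGAP1, an Arf GTPase-activating protein, from 0.797 ± 0.06 to 0.4 ± 0.057.

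PEX16 rose after U2AF2 knockdown from 0.24 ± 0.056 to 0.855 ± 0.078, and the non-coding KCTD21-AS1 from 0.2 ± 0.053 to 0.905 ± 0.049. AP2A1 rose to 0.83 ± 0.028, TMEM237, a protein of the ciliary transition zone, from 0.343 ± 0.068 to 1 ± 0, AC078860.2 from 0.011 ± 0.013 (n = 2) to 0.71 ± 0.156, and U47924.2 from 0.323 ± 0.023 to 0.93 ± 0.085, and in these 4 genes the last exon overlaps another gene. MYORG fell from 0.967 ± 0.029 to 0.455 ± 0.106, IQGAP2, a scaffold protein, from 0.937 ± 0.061 to 0.52 ± 0.071, and LNX2, a ubiquitin ligase, from 0.973 ± 0.023 to 0.625 ± 0.064. DDHD1 fell from 0.66 ± 0.04 to 0.295 ± 0.007 and PTER from 0.923 ± 0.098 to 0.52 ± 0.014, both with an overlapping gene. The remaining large falls were AC020915.2 to 0.27 ± 0.042, AC004264.1 to 0.375 ± 0.092 and AL513218.1 to 0.585 ± 0.064, which overlap ZNF544, LIF and CC2D1B.

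Of 32 tested HDAC corepressor genes, 7 rose and 2 fell in shU2AF2, 23 did not pass, and 7 rose and 4 fell adjusted over the list alone. HDAC4, a class II deacetylase, rose from 0.263 ± 0.042 to 0.665 ± 0.021, GATAD2A, of the NuRD complex, from 0.157 ± 0.023 to 0.26 ± 0.028, HDAC2 from 0.01 ± 0 to 0.05 ± 0 and SAP18 from 0.073 ± 0.006 to 0.12 ± 0. Of 46 neurodevelopmental disorder genes, 2 rose and 5 fell, or 2 and 6 adjusted over the list alone. TSC1 rose from 0.603 ± 0.032 to 1 ± 0 and NSD1, a histone methyltransferase, from 0.553 ± 0.035 to 0.815 ± 0.021, while MED13, of the Mediator kinase module, fell from 0.993 ± 0.012 to 0.71 ± 0.014 and ADNP from 0.473 ± 0.021 to 0.34 ± 0.042. Of 59 Rab and vesicle traffic genes, 4 rose and 4 fell, among the rises SNX2, whose direction turned with libraries centred, and 6 rose and 6 fell adjusted over the list alone. SEC22B, a vesicle SNARE, rose from 0.273 ± 0.025 to 0.56 ± 0.042 and STX7 from 0.097 ± 0.015 to 0.17 ± 0, while RAB21 fell from 0.293 ± 0.015 to 0.215 ± 0.007 and STX6 from 0.57 ± 0.052 to 0.405 ± 0.007, the latter pair with overlapping genes. Of 44 cell cycle genes 6 rose, also adjusted over the list alone, with CDT1 from 0.24 ± 0 to 0.53 ± 0.042 and MCM2 from 0.033 ± 0.006 to 0.08 ± 0, and the direction of MCM5 turned with libraries centred.

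Of 39 known 3' UTR polyadenylation targets, 4 rose and 1 fell in shU2AF2, or 7 and 2 adjusted over the list alone. TMEM106B, a lysosomal membrane protein, rose from 0.043 ± 0.006 to 0.15 ± 0.014 and RHEB from 0.1 ± 0.01 to 0.16 ± 0, and CSNK1A1, casein kinase 1 alpha, fell from 0.4 ± 0.03 to 0.305 ± 0.007 with an overlapping gene. Of 35 neurodegeneration genes 4 rose, also adjusted over the list alone, among them VCP, an AAA ATPase, from 0.25 ± 0.026 to 0.385 ± 0.021, and HTT to 0.22 ± 0, which stood at −0.004 against the other knockdowns. Of 20 microRNA pathway genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone, with AGO2 from 0.743 ± 0.093 to 1 ± 0 and CNOT6L down from 0.78 ± 0.078 to 0.525 ± 0.021. Of 31 nuclear RNA decay and export genes 4 rose and 1 fell, or 4 and 2 adjusted over the list alone. EXOSC6 fell from 0.257 ± 0.006 to 0.145 ± 0.007, and THOC5, of the THO export complex, rose from 0.033 ± 0.006 to 0.075 ± 0.007. In the U2 snRNP list 3 of 26 rose, also adjusted over the list alone, with SUGP1 from 0.02 ± 0.01 to 0.15 ± 0.028 and SF3B1 from 0.057 ± 0.006 to 0.095 ± 0.007. Of 44 ubiquitin genes 1 rose and 3 fell, or 2 and 3 adjusted over the list alone, with TRIM33 down to 0.66 ± 0.057 and UBE2H to 0.845 ± 0.049, and the rise was SKP1, at −0.013 with libraries centred.

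Of 20 SR protein genes, SRSF1 rose in shU2AF2 from 0.13 ± 0 to 0.335 ± 0.007, with an overlapping gene, and SRSF10 fell from 0.523 ± 0.015 to 0.39 ± 0.028, while 3 rose and 4 fell adjusted over the list alone. Of 37 oxidative phosphorylation genes 4 rose, NDUFV3 from 0.133 ± 0.006 to 0.215 ± 0.007, COX7B and UQCRB to 0.04 ± 0 and 0.045 ± 0.007, and NDUFA9 to 0.02 ± 0, at −0.013 with libraries centred, and 5 rose adjusted over the list alone. Of 36 hnRNP and KH-domain genes 3 rose, HNRNPA3 from 0.27 ± 0 to 0.455 ± 0.021, HNRNPDL to 0.415 ± 0.021 and HNRNPD to 0.075 ± 0.007, the last at −0.002 with libraries centred, and 4 rose and 4 fell adjusted over the list alone. Of 27 cleavage and polyadenylation factors CSTF1 rose from 0.133 ± 0.012 to 0.185 ± 0.021 and CPSF6 to 0.775 ± 0.007, also the 2 calls adjusted over the list alone. No list passed camera in shU2AF2, and by fry the neurodegeneration list was higher (adjusted p = 0.0445, and 0.491 with libraries centred).

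In shU2AF2 limma called 899 of 12362 genes, 727 higher and 172 lower, and 593 of them differed by at least 0.1. When shControl replicate 1 was left out, 788 genes were called, 614 higher and 174 lower, and 689 of the 899 kept their call. As rises and falls, members called without that library were 7 and 3 corepressor genes, 2 and 6 neurodevelopmental genes, 2 and 2 traffic genes, 4 and 0 cell cycle genes, 5 and 2 polyadenylation targets, 3 and 0 neurodegeneration genes, 2 and 1 microRNA pathway genes, 3 and 1 RNA decay and export genes, 3 and 0 U2 snRNP genes, 1 and 2 ubiquitin genes, 2 and 1 SR proteins, 4 and 0 oxidative phosphorylation genes, 3 and 0 hnRNP genes and 0 and 1 cleavage factors. Of the genes named for shU2AF2, CSTF1, CPSF6, HTT, CNOT6L, STX6, AC020915.2 and AL513218.1 lost their calls there (adjusted p = 0.0568 to 0.123). With libraries centred on their medians 391 genes were called, 259 higher and 132 lower, with only these 2 groups in the fit 327, and without shU2AF2 replicate 2 there were 573. Of the 899 differences, 27 changed direction with libraries centred, and 586 calls also passed against the other 5 knockdowns.

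The comparison of shPABPN1 with shControl concerns PABPN1, the nuclear poly(A)-binding protein that controls poly(A) tail length. MCTS1, a translation reinitiation factor, rose from 0.173 ± 0.031 to 0.71 ± 0.198, and SUGT1, a co-chaperone, from 0.13 ± 0.036 to 0.595 ± 0.12. BID, a pro-apoptotic BCL-2 family member, rose from 0.377 ± 0.081 to 0.835 ± 0.021 and ATL3, an atlastin of the endoplasmic reticulum, from 0.427 ± 0.107 to 0.895 ± 0.092. FOXD2, a forkhead transcription factor, fell from 0.937 ± 0.047 to 0.445 ± 0.007, a difference of −0.492 (SE 0.024, limma, adjusted p = 4.05e-05), in a last exon on chromosome 1 from 47436017 to 47440691. MED13 fell from 0.993 ± 0.012 to 0.56 ± 0.042, and HMX2, a homeobox transcription factor, from 0.89 ± 0.061 to 0.19 ± 0.057.

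Other large rises in shPABPN1 were FRA10AC1 from 0.353 ± 0.127 to 0.885 ± 0.163, CCDC50 from 0.39 ± 0.02 to 0.89 ± 0.156, and the non-coding genes AC099850.1 from 0.387 ± 0.17 to 0.955 ± 0.064 and EIF2AK3-DT from 0.437 ± 0.08 to 0.96 ± 0.057. AC009831.1 rose to 1 ± 0 from 0.433 ± 0.071 and HYMAI, an imprinted non-coding gene, from 0.15 ± 0.03 to 0.625 ± 0.064, which overlap TRAPPC8 and PLAGL1. PREX1, a Rac exchange factor, fell from 0.777 ± 0.012 to 0.365 ± 0.035, ZNF292 from 0.853 ± 0.076 to 0.5 ± 0.099 and FAM214B from 0.943 ± 0.074 to 0.575 ± 0.064. MME, which encodes neprilysin, fell from 0.74 ± 0.144 to 0.39 ± 0.085 and CENPBD1 from 0.817 ± 0.165 to 0.365 ± 0.021, and these overlap MME-AS1 and AFG3L1P. The non-coding AL353596.1 fell from 0.945 ± 0.078 (n = 2) to 0.455 ± 0.007 and AL121820.1 from 1 ± 0 to 0.615 ± 0.049.

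Of 38 tested known 3' UTR polyadenylation targets, 7 rose and none fell in shPABPN1, 31 did not pass, and 10 rose adjusted over the list alone. CD47, an immune checkpoint ligand, rose from 0.273 ± 0.032 to 0.55 ± 0.042 and TMEM106B from 0.043 ± 0.006 to 0.12 ± 0.014. ELAVL1, the RNA-binding protein HuR, rose from 0.117 ± 0.006 to 0.17 ± 0.014 with an overlapping gene. The list was higher than other genes by camera, with a median difference of 0.031 (adjusted p = 0.00241), but the adjusted p was 0.378 with an estimated correlation. By fry this list and the microRNA pathway list were higher (adjusted p = 0.0239 and 0.0302), which did not pass with libraries centred (adjusted p = 0.261 and 0.0723). Of 59 Rab and vesicle traffic genes 8 rose, also adjusted over the list alone, with SEC22B from 0.273 ± 0.025 to 0.48 ± 0.014, RAB22A from 0.107 ± 0.006 to 0.215 ± 0.035 and RAB11A from 0.13 ± 0 to 0.18 ± 0.014. Of 31 nuclear RNA decay and export genes 4 rose and 1 fell, or 7 and 2 adjusted over the list alone. EXOSC6 rose from 0.257 ± 0.006 to 0.41 ± 0.014 and NXF1, the messenger RNA export receptor, fell from 0.52 ± 0.017 to 0.39 ± 0.028. Of 36 hnRNP and KH-domain genes 4 rose, or 5 adjusted over the list alone, with HNRNPA3 from 0.27 ± 0 to 0.485 ± 0.007.

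Of 46 neurodevelopmental disorder genes, 2 rose and 2 fell in shPABPN1, or 3 and 4 adjusted over the list alone. PHF21A rose from 0.58 ± 0.056 to 0.865 ± 0.12, and NIPBL, the cohesin loader, fell from 0.2 ± 0.017 to 0.145 ± 0.007. Of 35 neurodegeneration genes 3 rose, also adjusted over the list alone, TMEM106B among them and HTT from 0.18 ± 0.01 to 0.25 ± 0.014. Of 20 microRNA pathway genes 3 rose, or 4 adjusted over the list alone, with TNRC6B from 0.35 ± 0.026 to 0.66 ± 0.127 and AGO2 from 0.743 ± 0.093 to 0.985 ± 0.021. Of 36 oxidative phosphorylation genes 3 rose, NDUFV3 from 0.133 ± 0.006 to 0.31 ± 0.028 with COX7B and NDUFA9, and 5 rose and 2 fell adjusted over the list alone. Of 32 HDAC corepressor genes HDAC5 rose from 0.223 ± 0.025 to 0.385 ± 0.007 while HDAC3 fell from 0.337 ± 0.032 to 0.255 ± 0.007 and ARID4A from 0.327 ± 0.015 to 0.205 ± 0.021, and 1 rose and 3 fell adjusted over the list alone. Of 27 cleavage and polyadenylation factors CPSF6 rose to 1 ± 0 and PPP1CB fell to 0.335 ± 0.007, also the 2 calls adjusted over the list alone. Of 20 SR proteins SRSF1, with its overlapping gene, rose to 0.265 ± 0.049 and SREK1 to 0.39 ± 0.014, with 3 adjusted over the list alone, and of 44 ubiquitin genes 2 rose, UBE2N to 0.325 ± 0.021 among them, with 5 adjusted over the list alone. None of 44 cell cycle or 26 U2 snRNP genes was called, with 0 and 2 adjusted over the list alone.

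In shPABPN1 limma called 579 of 12278 genes, 490 higher and 89 lower, and 350 differed by at least 0.1. Leaving out shControl replicate 1 gave 1048 calls, 519 higher and 529 lower, and 515 of the 579 kept their call. Rises no longer outnumbered falls there. Members called without shControl replicate 1, as rises and falls, were 8 and 0 polyadenylation targets, 6 and 2 traffic genes, 5 and 4 RNA decay and export genes, 6 and 2 hnRNP genes, 2 and 5 neurodevelopmental genes, 3 and 1 neurodegeneration genes, 3 and 0 microRNA pathway genes, 4 and 4 oxidative phosphorylation genes, 1 and 6 corepressor genes, 2 and 2 cleavage factors, 2 and 3 SR proteins, 3 and 1 ubiquitin genes, 1 and 4 cell cycle genes, and 1 and 2 U2 snRNP genes. Against the other 5 knockdowns 1288 genes were called, 480 higher and 808 lower, and 399 of the 579 calls passed there as well. Calls fell to 343 without shControl replicate 3 and 369 without shPABPN1 replicate 1, to 362 with libraries centred, 338 of them higher, and to 0 with only these 2 groups in the fit. At an unadjusted p under 0.05 the fit with every group had 2224 genes.

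The comparison of shPCBP2 with shControl concerns PCBP2, a KH-domain protein that binds C-rich RNA. RGS17, a regulator of G-protein signalling, rose from 0.613 ± 0.06 to 0.985 ± 0.021 (adjusted p = 0.018, and 0.0593 without shControl replicate 1) and NAAA, a lysosomal amidase, from 0.56 ± 0.106 to 0.94 ± 0.028. TMEM65, a mitochondrial membrane protein, rose from 0.26 ± 0.044 to 0.62 ± 0, a difference of 0.36 (SE 0.046, limma, adjusted p = 0.0102), in a last exon on chromosome 8 from 124306189 to 124314061. FOXD2 fell from 0.937 ± 0.047 to 0.575 ± 0.007, and AXIN2, a negative regulator of Wnt signalling, from 0.937 ± 0.061 to 0.65 ± 0.042.

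ZNF704 rose in shPCBP2 from 0.637 ± 0.021 to 1 ± 0, PCGF5, a Polycomb group protein, from 0.693 ± 0.035 to 1 ± 0, CAMK4, a calcium-dependent kinase, from 0.337 ± 0.093 to 0.675 ± 0.007, RBM4B from 0.61 ± 0.035 to 0.915 ± 0.078 and ADARB1, an RNA-editing deaminase, from 0.5 ± 0.062 to 0.78 ± 0.071. DDHD1 rose to 1 ± 0 and CPSF6 to 0.93 ± 0.099, both with an overlapping gene. E2F7, a cell cycle repressor, fell from 0.957 ± 0.051 to 0.73 ± 0.014, RRN3, an initiation factor of RNA polymerase I, from 0.97 ± 0.052 to 0.76 ± 0.028, LNX2 from 0.973 ± 0.023 to 0.715 ± 0.007 and RWDD4 from 1 ± 0 to 0.76 ± 0.028. The non-coding TSPEAR-AS1 fell from 1 ± 0 (n = 2) to 0.485 ± 0.092, AL162171.1 from 0.907 ± 0.07 to 0.555 ± 0.092, FAM243A from 0.94 ± 0.079 to 0.655 ± 0.035 and MME, with its overlap, to 0.33 ± 0.042.

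The calls of the lists in shPCBP2 were all rises. They were 2 of 37 hnRNP and KH-domain genes, HNRNPA3 from 0.27 ± 0 to 0.39 ± 0.014 and TARDBP, the TDP-43 gene, from 0.303 ± 0.029 to 0.43 ± 0, with an overlapping gene, the latter also the 1 call of 35 neurodegeneration genes. MTREX, the exosome helicase, which overlaps PLPP1, rose from 0.053 ± 0.015 to 0.17 ± 0 and EXOSC6 to 0.305 ± 0.007 among 31 RNA decay and export genes. AGO2 rose to 1 ± 0 and AGO1, with an overlapping gene, to 0.985 ± 0.021 among 20 microRNA pathway genes. SEC22B rose to 0.42 ± 0 and STX7 to 0.155 ± 0.007 among 58 traffic genes, and SREK1 from 0.3 ± 0.01 to 0.435 ± 0.007 among 20 SR proteins. MCM2 rose to 0.08 ± 0 among 44 cell cycle genes, and CPSF6 rose among 27 cleavage factors. Adjusted over the list alone the rises were 2, 3, 2, 2, 2, 1, 1 and 1 in these 8 lists in the order given, with 1 fall among the SR proteins. None was called among 38 polyadenylation targets, 46 neurodevelopmental, 36 oxidative phosphorylation, 32 corepressor, 26 U2 snRNP and 44 ubiquitin genes, and adjusted over the list alone 2 polyadenylation targets and 1 oxidative phosphorylation gene rose. Without shControl replicate 1, members called were 2 hnRNP, 1 neurodegeneration, 1 RNA decay and export, 1 microRNA pathway, 0 traffic, 1 SR protein, 1 cell cycle and 1 cleavage factor gene, all rises. No list passed camera or fry.

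In shPCBP2 limma called 145 of 12434 genes, 130 higher and 15 lower, and 93 differed by at least 0.1. Without shControl replicate 1 there were 58 calls, 52 higher and 6 lower, and 54 of the 145 kept their call. Of the genes named for shPCBP2, NAAA, RGS17, ZNF704, CAMK4, PCGF5, RBM4B, TSPEAR-AS1, AL162171.1, AXIN2, LNX2, RWDD4, E2F7, AGO1, EXOSC6, SEC22B and STX7 lost their calls there (adjusted p = 0.0508 to 0.147). Calls numbered 55 without shControl replicate 3 and 46 without either shPCBP2 replicate 1 or 2, with 28 higher and 18 lower, and 29 higher and 17 lower. There were 2 with only these 2 groups in the fit, and 4 with libraries centred, where 8 of the 145 differences changed direction. Against the other 5 knockdowns 159 genes were called, 83 higher and 76 lower, and 56 of the 145 calls passed there as well.

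The comparison of shZNF384 with shControl concerns ZNF384, a zinc finger transcription factor. IFNAR2, an interferon receptor subunit whose last exon overlaps other genes, rose from 0.603 ± 0.067 to 0.995 ± 0.007, and ATL3 rose from 0.427 ± 0.107 to 0.955 ± 0.064. RGS17 rose from 0.613 ± 0.06 to 0.985 ± 0.007, a difference of 0.372 (SE 0.055, limma, adjusted p = 0.0202), in a last exon on chromosome 6 from 153010722 to 153011762. Its adjusted p was 0.0631 without shControl replicate 1 and 0.408 against the other 5 knockdowns. HNRNPC, an RNA-binding protein, fell from 0.177 ± 0.006 to 0.14 ± 0, and CELF2, a regulator of splicing, from 0.273 ± 0.032 to 0.145 ± 0.007. The other falls were HMX2 from 0.89 ± 0.061 to 0.475 ± 0.021, SNAI3 from 0.99 ± 0.014 (n = 2) to 0.77 ± 0.014, AL355488.1 from 0.94 ± 0.061 to 0.74 ± 0, FOXD2 to 0.805 ± 0.021, UQCR11, of respiratory complex III, from 0.23 ± 0.026 to 0.125 ± 0.007, and ENOSF1, which overlaps TYMS, from 0.987 ± 0.023 to 0.665 ± 0.021.

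HSF2BP rose in shZNF384 from 0.185 ± 0.12 (n = 2) to 0.89 ± 0.156, BID from 0.377 ± 0.081 to 0.765 ± 0.106, ZNF213 from 0.54 ± 0.053 to 0.905 ± 0.064, REM2, a small GTPase, from 0.643 ± 0.045 to 1 ± 0 and MAP3K9, a kinase, from 0.44 ± 0.087 to 0.79 ± 0.099. JAM2, a junctional adhesion molecule, rose from 0.57 ± 0.061 to 0.99 ± 0.014 and AVL9 from 0.647 ± 0.049 to 0.98 ± 0.028, both with an overlapping gene. In the lists, 3 of 38 polyadenylation targets rose, among them TMEM106B to 0.13 ± 0.014, also the 1 call of 35 neurodegeneration genes, and 1 of 46 neurodevelopmental genes rose. HNRNPA3 rose to 0.4 ± 0.014 and HNRNPC fell among 36 hnRNP genes. Among 20 microRNA pathway genes AGO2 rose to 1 ± 0 and AGO1, with an overlapping gene, to 0.985 ± 0.021. STX7 rose to 0.16 ± 0.014 and SEC22B to 0.395 ± 0.021 among 58 traffic genes, although SEC22B stood at −0.006 against the other knockdowns, and UBE2V2 to 0.205 ± 0.007 among 44 ubiquitin genes. CPSF6 rose to 0.875 ± 0.049 and CPSF2 to 0.085 ± 0.007 among 27 cleavage factors and MCM2 to 0.075 ± 0.007 among 44 cell cycle genes, but CPSF2 and MCM2 turned to −0.01 and −0.007 with libraries centred. Adjusted over the list alone, the rises were 5, 4, 2, 3, 3, 5, 1, 2 and 1 in these 9 lists in the order given, with 1 fall each among neurodevelopmental and hnRNP genes.

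None of 31 RNA decay and export, 36 oxidative phosphorylation, 20 SR protein, 32 corepressor and 26 U2 snRNP genes was called in shZNF384. Adjusted over the list alone, 3 RNA decay and export genes and 2 oxidative phosphorylation genes rose, and 2 SR protein genes rose and 1 fell. Without shControl replicate 1 the members called were 3 polyadenylation targets and 1 gene each of the neurodegeneration, hnRNP and microRNA pathway lists, all rises. No list passed camera. By fry the polyadenylation targets, microRNA pathway, traffic, neurodegeneration and ubiquitin lists were higher in shZNF384 (adjusted p = 0.0247 to 0.0336), and all 5 turned lower, without passing, with libraries centred. In shZNF384 limma called 188 of 12541 genes, 180 higher and 8 lower, and 113 differed by at least 0.1. With shControl replicate 1 left out there were 63 calls, 61 higher and 2 lower, and 55 of the 188 kept their call. Of the genes named for shZNF384, only ATL3, IFNAR2, FOXD2, HNRNPA3, AGO2 and TMEM106B were among the calls there, HSF2BP and SNAI3 could not be tested, and the others, HNRNPC and CELF2 included, lost their calls (adjusted p = 0.0546 to 0.118). Without shZNF384 replicate 1 there were 38, 26 higher and 12 lower, and without shZNF384 replicate 2 there were 29, 23 higher and 6 lower. Calls numbered 22 without shControl replicate 3, 100 and 103 without shHDAC1 replicates 1 and 2, 121 without either shPCBP2 library and 119 without shU2AF2 replicate 1. At an unadjusted p under 0.05 there were 1727 genes. There were 5 calls with only these 2 groups in the fit, 0 with libraries centred, where 31 of the 188 differences changed direction, and 74 against the other 5 knockdowns, of which 36 were among the 188.

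The comparison of shHDAC1 with shControl concerns HDAC1, a class I histone deacetylase, and 3 genes passed the test, all lower. JMJD6, a lysyl hydroxylase, fell from 1 ± 0 (n = 2) to 0.805 ± 0.007, a difference of −0.195 (SE 0.004, limma, adjusted p = 1.92e-07), in a last exon on chromosome 17 from 76712832 to 76716722. AFAP1, an actin filament-associated protein, fell from 1 ± 0 to 0.905 ± 0.007 (adjusted p = 5.99e-07), and FAM199X from 0.983 ± 0.015 to 0.845 ± 0.021 (adjusted p = 0.00688). JMJD6 and AFAP1 also stood at 1 ± 0 in the other 5 knockdowns. The small errors of JMJD6 and AFAP1 rest on values at the upper end of the scale. All 3 calls also passed without shControl replicate 1 and against the other 5 knockdowns, but 1 passed with a robust prior and 0 with genes that lack spread left out of the limma fit, where the adjusted p of JMJD6 was 0.0558.

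No member of the 14 lists was called in shHDAC1. The microRNA pathway list was lower than other genes by camera, with a median difference of −0.017 over 20 genes (adjusted p = 0.0373), and the adjusted p was 0.378 with an estimated correlation and 0.0709 by fry. Adjusted over the list alone, 1 microRNA pathway gene, 1 RNA decay and export gene and 2 SR protein genes fell, and none passed in the other 11 lists. At an unadjusted p under 0.05 there were 740 of 12371 genes. Against the other 5 knockdowns limma called 669 genes, 63 higher and 606 lower, so that shHDAC1 differed from the other knockdowns in more genes than from shControl. Calls against shControl numbered 4 without shControl replicate 1, 6 without shControl replicate 3, 31 and 51 without shHDAC1 replicates 1 and 2, 5 without either shSF3B4 library, and 0 with libraries centred.

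**Figure D2:**
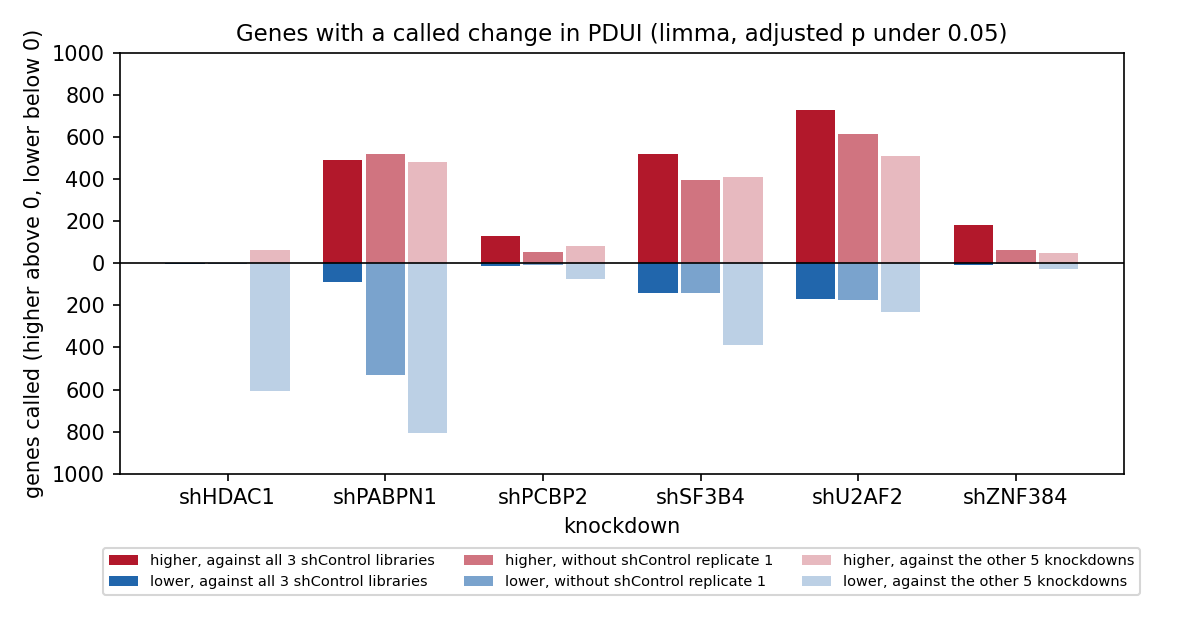
Number of genes with a called change in PDUI (limma, adjusted p under 0.05) in each knockdown on the x axis, with rises above 0 and falls below it, against all 3 shControl libraries, without shControl replicate 1 and against the other 5 knockdowns. In shPABPN1 the falls went from 89 to 529 and 808 across these references, and in shHDAC1 from 3 to 4 and 606.

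The mean of all 6 knockdowns was compared with shControl. GYG2, a glycogenin, rose from 0.807 ± 0.035 to 0.986 ± 0.029 over 12 knockdown libraries (limma, adjusted p = 0.00341), NFE2L3, a transcription factor, from 0.12 ± 0.026 to 0.222 ± 0.061, ZNF704 from 0.637 ± 0.021 to 0.903 ± 0.137 and RTCA, an RNA cyclase, from 0.243 ± 0.029 to 0.362 ± 0.069. HSPA4L, a heat shock protein, rose from 0.133 ± 0.006 to 0.182 ± 0.03, COMMD3 from 0.183 ± 0.012 to 0.293 ± 0.06, ELP5, of the Elongator complex, from 0.383 ± 0.055 to 0.584 ± 0.186 and FKBP11 from 0.617 ± 0.015 to 0.762 ± 0.121, and these 4 overlap another gene. E2F7 fell from 0.957 ± 0.051 to 0.763 ± 0.063 and MME, with its overlap, from 0.74 ± 0.144 to 0.393 ± 0.059. In these genes all 12 knockdown libraries lay on 1 side of the controls.

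Over 11449 genes limma called 389 for all knockdowns together, 356 higher and 33 lower, of which 148 differed by at least 0.1. Every knockdown library lay beyond the control range in 23 of the 389, so most of these calls were not shared by every library. For a gene not chosen by its difference, chance gives a share of 0.0022 in each direction. The 389 were chosen by their difference, so that share is no comparison for them. Mean PDUI was 0.563 ± 0.0151 in the 12 knockdown libraries and 0.548 ± 0.0224 in the 3 controls (exact permutation test over 455 splits, p = 0.163). Calls numbered 137 without shControl replicate 1, 122 higher and 15 lower. They numbered 204 and 108 without shControl replicates 2 and 3, and 4 with libraries centred.

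Differences among the 6 knockdowns use no control mean, and limma found 1474 of 11463 genes by F-test. RPAP2, an RNA polymerase II phosphatase, had the values 0.37 ± 0 in shSF3B4, 0.16 ± 0 in shU2AF2 and 0.04 to 0.08 in the other 4 knockdowns (F-test adjusted p = 7.29e-06). DGAT1, an enzyme of triglyceride synthesis, reached 0.37 ± 0 in shU2AF2 and 0.295 ± 0.007 in shSF3B4 with 0.11 to 0.2 elsewhere, and MAPK1IP1L reached 0.77 ± 0 in shU2AF2 and 0.47 ± 0 in shSF3B4 with 0.29 to 0.4 elsewhere. SH3PXD2A, a podosome scaffold, stood at 0.465 ± 0.021 in shSF3B4 and 0.475 ± 0.007 in shU2AF2 with 0.16 to 0.265 elsewhere, and PLXNA3, a semaphorin receptor, at 0.095 ± 0.007 and 0.13 ± 0 with 0.02 to 0.03 elsewhere. JMJD6, AFAP1, AP2A1, EXOSC6 and AC010327.6 were the others of the 10 with the smallest p. With libraries centred, 904 genes passed the F-test.

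Some genes moved in opposite directions in different knockdowns, with a called difference between the knockdowns as well. That difference adds up both called changes in the same fit, so its call follows nearly by construction and is no added support. The genes named here were chosen after their values were seen. DDHD1 stood at 0.66 in shControl, at 1 in shPABPN1 and shPCBP2, and at 0.2 and 0.295 in shSF3B4 and shU2AF2. CPSF6 stood at 0.597 in shControl, at 1 in shPABPN1 and at 0.415 in shSF3B4, where its call was lost without shControl replicate 1 (limma, adjusted p = 0.0915). EXOSC6 went from 0.257 in shControl to 0.41 in shPABPN1 and to 0.145 in shU2AF2, and SREK1 from 0.3 to 0.435 in shPCBP2 and 0.16 in shSF3B4. BCLAF1, a splicing-associated factor, went from 0.233 to 0.31 in shPCBP2 and 0.145 in shSF3B4. In shPABPN1 and shSF3B4, 33 genes were called in opposite directions, and 26 without shControl replicate 1. In shSF3B4 and shU2AF2 they were 7, and 2 without that library.

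**Figure D3:**
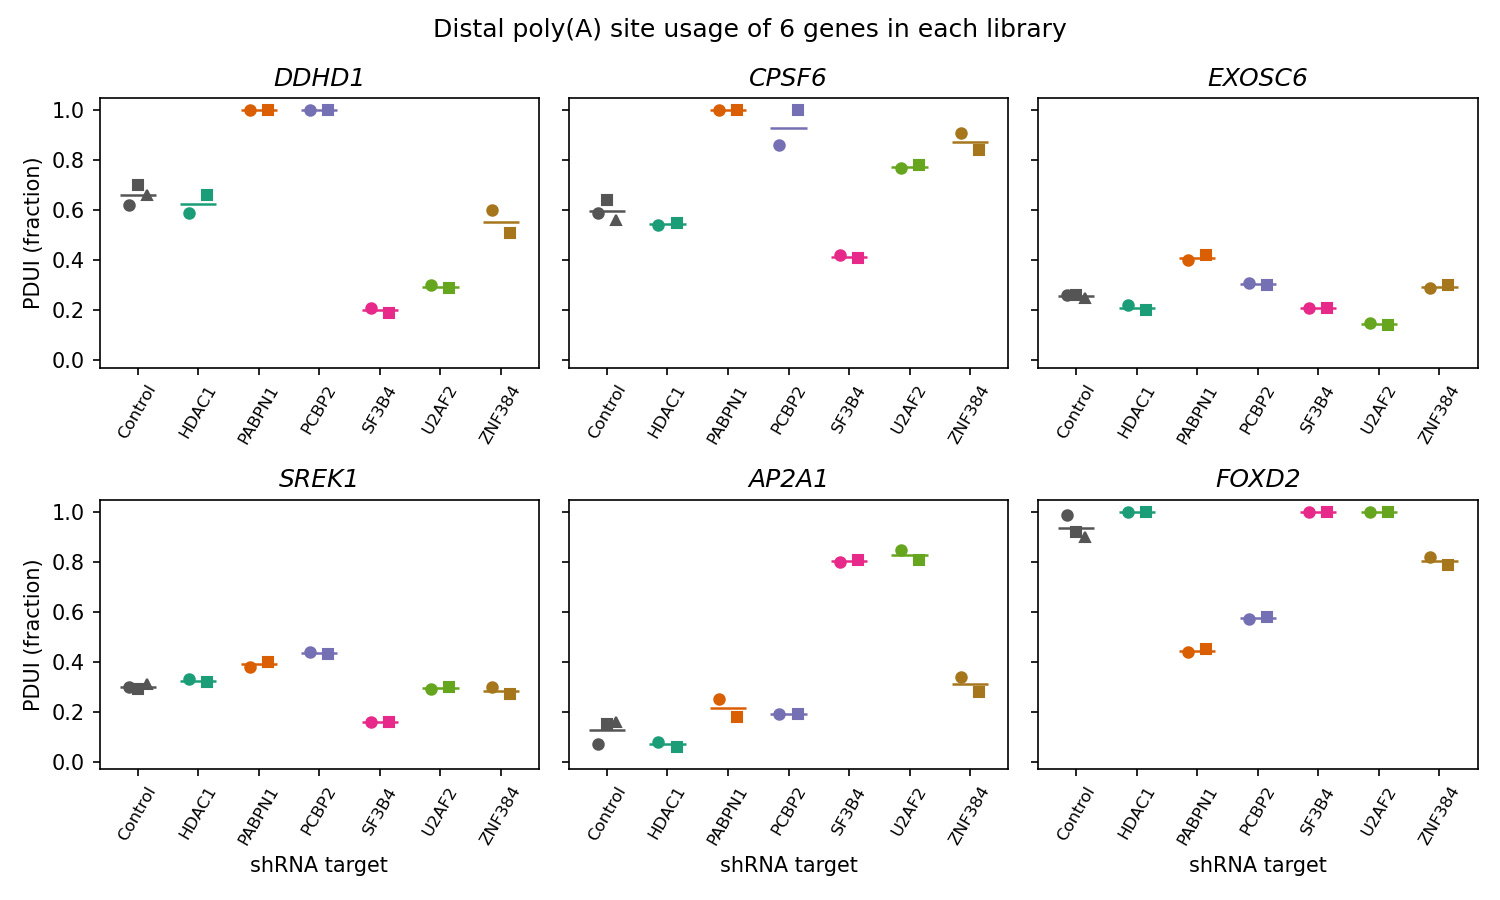
PDUI (fraction, y axis) of DDHD1, CPSF6, EXOSC6, SREK1, AP2A1 and FOXD2 in each of the 15 libraries, by target of the hairpin on the x axis, with a symbol per replicate and a line at the group mean. DDHD1 lies at 1 in the shPABPN1 and shPCBP2 libraries and at 0.19 to 0.3 in the shSF3B4 and shU2AF2 libraries, and AP2A1 lies at 0.8 to 0.85 in the latter 4.

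Shared calls were counted for each pair of knockdowns. In shSF3B4 and shU2AF2, 309 genes rose in common, where 31 would be shared if calls were independent, and 47 fell, where chance gives 2. AP2A1, PEX16, TSC1 and CDT1 rose in both, and TRIM33, UBE2H and SRSF10 fell in both, also without shControl replicate 1. Across 11353 genes the changes in these knockdowns correlated at r = 0.479, where unchanged groups that share the controls gave 0.404 in simulations, and at r = 0.357 against 0.204 with the other knockdowns as the reference. For shPCBP2 and shZNF384, whose common rises numbered 60 where chance gives 1.9, r was 0.544 against 0.399, and 0.425 against 0.202 with the other knockdowns as the reference. Genes are not independent replicates, and shared controls raise shared calls above such chance numbers. The simulated libraries had 1 spread per gene and no knockdown effects, although shControl replicate 1 had the lowest array weight (0.373). With the other knockdowns as the reference, their own effects enter both changes and can raise r. The pair of shHDAC1 and shPCBP2 stood at 0.314 against 0.198 there. A value above the simulated one therefore does not by itself show similar effects. A direct comparison of shPCBP2 with shZNF384 called 9 of 12382 genes, while shSF3B4 and shU2AF2 differed in 478 of 12091 and shPABPN1 and shSF3B4 in 1170 of 11920. Covariance exceeded its simulated value in 10 of the 15 pairs against shControl and in 10 against the other knockdowns, but these were not the same pairs. The pair of shHDAC1 and shPCBP2, for example, exceeded it only against the other knockdowns, and that of shPCBP2 and shSF3B4 only against shControl. By r against shControl, the simulated value was exceeded for shSF3B4 and shU2AF2, for shPCBP2 and shZNF384, for shPCBP2 and shU2AF2 (0.44 against 0.397) and for shU2AF2 and shZNF384 (0.439 against 0.402), and in no other pair.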

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

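The tests of shControl replicate 1, of the control library alone, of differently prepared controls and of the reference level, and the counts of opposite calls without shControl replicate 1, were chosen only after the results were seen. Apart from that for the missing values, the intervals in this section were taken over genes. These genes share the same libraries and are not independent replicates. The intervals do not measure the spread between libraries, so what they argue against holds for these libraries only.

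Some genes were called higher in 1 knockdown and lower in another, each against shControl, and the difference between the knockdowns was itself called by limma. This last call follows nearly by construction, as the difference adds up both changes in the same fit, and it is no added support. There were 33 such genes for shPABPN1 and shSF3B4, 17 for shPABPN1 and shU2AF2, 17 for shPCBP2 and shSF3B4, 11 for shSF3B4 and shZNF384, 7 for shSF3B4 and shU2AF2, 6 for shPCBP2 and shU2AF2 and 6 for shU2AF2 and shZNF384. Without shControl replicate 1 the counts were 26, 17, 7, 4, 2, 3 and 4 in the same order, and the genes found both with and without that library numbered 19, 10, 5, 2, 2, 1 and 1. With libraries centred on their medians limma called 0 genes in shZNF384, where 1727 had an unadjusted p under 0.05 before centring, and 4 in shPCBP2, so no opposite call with shZNF384 and at most 4 with shPCBP2 remain possible there, and the other pairs were not counted with libraries centred. UBA6, a ubiquitin-activating enzyme, stood at 0.143 in shControl, at 0.21 in shPABPN1 and 0.195 in shPCBP2, and at 0.08 in shSF3B4 and 0.1 in shU2AF2. TSC22D2 stood at 0.16 in shControl, at 0.21 in shPABPN1 and shZNF384 and 0.215 in shPCBP2, and at 0.095 in shSF3B4 and 0.1 in shU2AF2. WDR26 stood at 0.453 in shControl, at 0.61 in shPABPN1 and 0.62 in shZNF384, and at 0.265 in shSF3B4 and 0.32 in shU2AF2. These 3 genes were chosen after their values were seen, and each knockdown mean has n = 2.

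The first pattern weighed is the distance of shControl replicate 1 from the other control libraries, by −0.0388 in mean PDUI. A whole swap with shPABPN1 cells is argued against, since the library carried a median share of 0.273 of the shPABPN1 change (interval 0.238 to 0.31, 1286 genes), beside 0 for the difference between the other control libraries. A shift of all genes alike is argued against by a correlation of 0.263 with the shPABPN1 change across genes, which are not independent replicates, once the trend with mean PDUI was removed (interval 0.246 to 0.28), beside −0.022 for the other controls. The number of missing values predicted a change of only −0.0075 (interval −0.0171 to 0.0021). A partial mixture with shPABPN1 material, or a difference in culture or library preparation, stays open, and no biological explanation was tested.

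The second pattern is the higher PDUI of the 6 knockdowns together. In a fit of 2 groups the real split called 2 genes, and 19 of 100 splits drawn from 455 called as many. The highest of the others called 244 with both shSF3B4 libraries and shU2AF2 replicate 1 on the control side, which points to a structure of the samples. That fit treats the 6 knockdowns as 1 group, so their differences enter its spread and the calls of other splits. It therefore cannot decide whether chance made the 389 calls of the fit with every group, and chance is not excluded. Without shControl replicate 1 the median difference was 0 rather than 0.0108, so that library may account for the median, but 89.1% of the 137 calls without it were still higher (interval 82.6 to 93.7). A preparation that sets the controls, whose library names alone carry the suffix nuc, apart from every knockdown library as the whole cause is argued against by shHDAC1, which carried a share of −0.021 of the change of the other 5 knockdowns (interval −0.056 to 0, 620 genes). What the 5 other knockdowns have in common, and a preparation that accounts for part of the difference, stay open, and no biological explanation was tested.

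The third pattern is the excess of rises over falls in shSF3B4 and shU2AF2. Reads of overlapping genes are argued against, since among calls without an overlap 79.3% were rises in shSF3B4 (interval 75.3 to 82.8, n = 473) and 78.5% in shU2AF2 (interval 75 to 81.7, n = 609). The room to rise at a low PDUI cannot be told apart from a true excess. Calls with a mean PDUI of at least 0.5 were rises in 54.3% (interval 46.3 to 62.2, n = 162) and 57.8% (interval 51.4 to 64, n = 251), beside 86.6% and 89.8% of the other calls. These intervals reach neither verdict set for the test. On the logit scale rises were 76.3% of 654 calls in shSF3B4 and 82.5% of 885 in shU2AF2. The excess stayed on that scale, which does not remove a shift of a whole library. With libraries centred on their medians, rises were 52.9% of 210 calls in shSF3B4 and 66.2% of 391 in shU2AF2. Centring subtracts a constant whether a shift is real or not, so these shares do not decide the cause. The split by mean PDUI leaves the cause of the excess open as well. Against the other 5 knockdowns 51.4% of the shSF3B4 calls were rises (interval 47.9 to 54.9, n = 801). That reference holds shU2AF2, which shared 309 rises with shSF3B4, so it also cancels rises that knockdowns have in common. The share thus cannot tell the level of the control libraries from such rises. Of the shU2AF2 calls 68.7% were rises (interval 65.2 to 72, n = 744), which argues against the reference level as the whole cause for shU2AF2. A direct effect of SF3B4 or U2AF2 on the choice of the poly(A) site stays open as untested.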

How the results depend on the processing

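The fits without genes that lack spread, the fit without the shSF3B4 libraries and without a block, the gene lists without shControl replicate 1, and fry on centred libraries and against the other knockdowns were chosen only after the results were seen. Calls are limma calls, and for each count below that changed by more than 1.5 times the cause was not tested unless it is stated.

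The fit of only the complete genes kept the direction and the side of the threshold of all 253 named results it covers, and array weights of 262 of 271. Fewer were kept with libraries centred (124 of 271, with 134 that lost their call and 13 reversed), with the block (81 of 191, 109 lost and 1 reversed), against the other 5 knockdowns (167 of 237, 66 lost and 4 reversed) and without shControl replicate 3 (183 of 264, 80 lost and 1 reversed), replicate 2 (206 of 266, 59 lost and 1 reversed) or replicate 1 (214 of 269, 55 lost). Named results include the targeted genes, most of which were never called.

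With only the 2 compared groups fitted, calls numbered 0 in shPABPN1, 2 in shPCBP2, 186 in shSF3B4, 327 in shU2AF2 and 5 in shZNF384. Fewer libraries set the spread and controls weigh more in it, so the cause is open. At an unadjusted p under 0.05 the fit of all groups had 2224 genes in shPABPN1. Of 251 named results 55 were kept, 196 lost their call and none reversed.

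With libraries centred on their medians, calls numbered 0 in shHDAC1, 362 in shPABPN1, 4 in shPCBP2, 210 in shSF3B4, 391 in shU2AF2, 0 in shZNF384, 4 for all knockdowns together and 904 among knockdowns. At an unadjusted p under 0.05 the uncentred limma fit had 740 genes in shHDAC1 and 1727 in shZNF384. The median differences turned to −0.015 in shHDAC1, 0.0117 in shPABPN1, −0.0183 in shPCBP2, −0.0167 in shSF3B4, −0.0117 in shU2AF2 and −0.0233 in shZNF384. By construction, centring subtracts the median of a library from all its genes alike, whether a shift is real or not. That median was 0.51 in shControl replicate 1 and 0.58 in the other control libraries. The constants exceeded the typical difference, so the median differences took the opposite sign instead of vanishing. A gene with a smaller difference than the constant had to reverse, which says nothing on whether that gene changed. Reversed were, in shSF3B4, HNRNPD (−0.002), SRSF3 (−0.013), SKP1 (−0.008), THOC5 (−0.007), NDUFA9 (−0.018), COX7B (−0.007) and SF3B4 itself (−0.007), in shU2AF2 HNRNPD (−0.002), SKP1 (−0.013) and NDUFA9 (−0.013), in shZNF384 CPSF2 (−0.01) and MCM2 (−0.007), and PCBP2 in its own knockdown (−0.013).

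Against the mean of the other 5 knockdowns calls numbered 669 in shHDAC1, 1288 in shPABPN1 and 74 in shZNF384, and the other 3 knockdowns stayed within 1.5 times their count. Reversed were HNRNPA3 in shSF3B4 (−0.054), HTT in shU2AF2 (−0.004), and FOXD2 (0.001) and SEC22B (−0.006) in shZNF384. The reference differs by construction, so these values answer another question.

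The replicate numbers of the titles entered a block in a fit without the shSF3B4 libraries. With this block calls numbered 6 in shHDAC1, 232 in shPABPN1, 7 in shPCBP2, 531 in shU2AF2 and 3 in shZNF384, and without it 5, 509, 95, 840 and 131. The medians with the block were 0.005, −0.005, 0.02, 0.015 and 0.03, and HDAC1 in its own knockdown turned to 0.02. Replicate numbers showed no pairing, with correlations of −0.012 to 0.047 across 15 pairs of groups. Once shSF3B4 is left out, replicate 3 occurs only in shControl, so the block fits that library exactly and takes it out of every comparison. The medians with the block equal those without shControl replicate 3. This setting thus rests on the other control libraries and fewer residual degrees of freedom, and is no test of pairing. Blocks by the numbers of the library names were not run, since they equal those of the titles once shSF3B4 is left out.

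Other settings moved fewer counts. In shHDAC1 there were 13 calls on the logit scale, 8 with the permissive filter, 5 with array weights, 1 with a robust prior and 0 without genes that lack spread, where 740 genes had an unadjusted p under 0.05 in the first limma fit. In shZNF384 there were 120 with a prior without a trend and also 120 without genes that lack spread. By construction a minimum change lowers counts: at least 0.1 left 350 calls in shPABPN1, 93 in shPCBP2, 410 in shSF3B4, 593 in shU2AF2, 113 in shZNF384 and 148 for all knockdowns, and at least 0.2 left 168, 45, 188, 310, 44 and 31, with 0 in shHDAC1. Of the gene lists 2 passed camera at the preset correlation, 0 with an estimated one, 5 against the other knockdowns, 3 with the block and 2 without shControl replicate 1. With the block the microRNA pathway list of shHDAC1 was lost (adjusted p = 0.0617), and the polyadenylation targets of shHDAC1 (0.0282) and the microRNA pathway list of shPABPN1 (0.0279) were gained. By fry 11 passed, 0 with libraries centred, where 8 of the 11 turned direction, and 7 against the other knockdowns, of which 1 was among the 11. The covariance of effects exceeded its simulated value in 10 of 15 pairs with either reference, though not in the same pairs. The alternative of 1 transcript per gene was not run, since the table holds 1 for each.

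Leaving out each library in turn gave 3 to 51 calls in shHDAC1, 343 to 1048 in shPABPN1, 46 to 158 in shPCBP2, 429 to 662 in shSF3B4, 573 to 855 in shU2AF2, 22 to 213 in shZNF384, 108 to 477 for all knockdowns and 1097 to 1896 among knockdowns. Median differences ranged from 0 to 0.005 in shHDAC1, −0.02 to −0.0033 in shPABPN1, 0.005 to 0.02 in shPCBP2, 0 to 0.02 in shSF3B4, 0 to 0.015 in shU2AF2 and 0.01 to 0.03 in shZNF384. With shControl replicate 1 left out, calls numbered 1048 in shPABPN1, 58 in shPCBP2, 63 in shZNF384 and 137 for all knockdowns, without replicate 2 of shControl 204 for all knockdowns, and without replicate 3 of shControl 6 in shHDAC1, 343 in shPABPN1, 55 in shPCBP2, 22 in shZNF384 and 108 for all knockdowns. Of a group's own libraries, shHDAC1 replicates 1 and 2 gave 31 and 51, shPABPN1 replicate 1 gave 369, either shPCBP2 library 46, shSF3B4 replicate 2 gave 429, shU2AF2 replicate 2 gave 573, and shZNF384 replicates 1 and 2 gave 38 and 29. The lone library left is then assumed to vary like the other groups. Libraries outside the comparison moved shZNF384 to 100 and 103 (shHDAC1 replicates 1 and 2), 121 (either shPCBP2 library) and 119 (shU2AF2 replicate 1), and shHDAC1 to 5 (either shSF3B4 library), which they can do only through the pooled spread and its prior. HDAC1 in its own knockdown turned to 0.03 without replicate 2 of shControl, 0.02 without replicate 3 and 0.003 without shHDAC1 replicate 2, in a range from −0.055 to 0.03, and PABPN1 in its own to −0.023 without shPABPN1 replicate 1, in a range from −0.023 to 0.067. Depth is unknown, so no result could be set beside it.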

Other observations

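The gene families and last exon lengths below were all chosen, and their tests run, only after the results were seen. They cover 5 knockdowns, and shHDAC1, with 3 calls, was left out.

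Of 48 tested genes for cytosolic ribosomal proteins, 10 rose and none fell in shPABPN1. RPS29 rose from 0.123 to 0.415, RPL37 from 0.117 to 0.34, RPS28 from 0.29 to 0.625 and RPS15A from 0.03 to 0.105 (limma, adjusted p = 0.000943, 0.000494, 0.0159 and 5.33e-05, with 3 shControl and 2 shPABPN1 libraries). The share called was 20.83% beside 4.65% of the other genes (Fisher's exact test, adjusted p = 0.0026 over 40 tests), where genes are not independent replicates. A call also depends on how precisely PDUI is measured, and depth is unknown, so this share cannot be read as a response of the family. In the other 4 knockdowns examined the share did not pass, with 6 of 49 called in shSF3B4 (adjusted p = 0.24), 8 of 49 in shU2AF2 (0.137), 2 of 49 in shZNF384 (0.445) and 0 of 49 in shPCBP2 (1). All 10 were also called without shControl replicate 1 and against the other 5 knockdowns.

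Of 68 tested mitochondrial ribosomal protein genes 9 rose and none fell in shU2AF2, of which MRPS23 turned direction with libraries centred on their medians. This is 13.24% beside 7.24% of the other genes, which did not pass (Fisher's exact test, adjusted p = 0.322). MRPL42 rose from 0.0933 in shControl to 0.325 in shPABPN1, 0.275 in shPCBP2, 0.35 in shU2AF2 and 0.265 in shZNF384, and stood at 0.105 in shSF3B4 and 0.085 in shHDAC1. MRPL35 rose from 0.383 to 0.765 in shPABPN1, 0.64 in shPCBP2, 0.655 in shU2AF2 and 0.635 in shZNF384, and its calls in shPCBP2 and shZNF384 were lost without shControl replicate 1 (limma, adjusted p = 0.104 and 0.106).

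Long non-coding genes were called less often than other genes in shPABPN1, 35 of 1241 or 2.82% beside 4.93% (Fisher's exact test, adjusted p = 0.0103), and in shU2AF2, 66 of 1260 or 5.24% beside 7.5% (adjusted p = 0.0381). No difference passed this test in the other 3 knockdowns examined, with 1.17% beside 1.17% in shPCBP2 (adjusted p = 1), 4.46% beside 5.52% in shSF3B4 (adjusted p = 0.426) and 1.37% beside 1.51% in shZNF384 (adjusted p = 1). Among the 35 were EIF2AK3-DT, FIRRE and HYMAI, which rose, and SNHG3, which fell in shPABPN1. The class follows the gene types of the matched GENCODE entries, and PDK3, a kinase gene, was counted among its rises. Genes are not independent replicates, and a call also depends on how precisely PDUI is measured. Depth is unknown, so these shares cannot be read as a weaker response of long non-coding genes.

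Last exon lengths were compared between genes with and without a call. The median length for genes that rose was 3543 bases in shPABPN1, 4297 in shPCBP2, 2650.5 in shSF3B4, 2564 in shU2AF2 and 3159 in shZNF384, for genes that fell 1809, 1884, 3515, 2968 and 2592, and for genes without a call 1344, 1358, 1347, 1316 and 1361. These lengths were not tested.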
